A study of Saccharomyces cerevisiae with 42 samples.

How the data were processed

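The series holds 42 single-colour Affymetrix arrays of Saccharomyces cerevisiae total RNA, 2 replicates at each of 7 times (before heat and 5 to 30 min at 39 C) in 3 strains: a parental strain, a deletion of DPL1 and a double deletion of LCB4 and LCB5. Strain, time and replicate number were taken from the sample labels. The labels give the deletion strains' genotypes with a KanMX marker and the parental genotype without it.

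The values used are those the authors deposited, on a log2 scale after the RMA procedure (background correction, quantile normalisation between arrays and a summary of the probes of each probe set), which the submitters' processing notes name. The log base is not stated in the sources used here and was inferred from the range of the values, 1.36 to 14.7; the version of the RMA software is not given in the sources used here. Quantile normalisation gives every array nearly the same distribution, so a shift of all transcripts together would not be seen, and array medians lay between 5.61 and 5.80. Precision is limited by the number of arrays, and no depth applies.

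The table holds 9335 probe sets, 60 of them AFFX controls. Of the 9275 others, 6504 have 1 gene symbol in the platform annotation, 328 have several and 2443 have none listed. Symbols were updated through gene identifiers against a RefSeq gene table, which changed 0 of them. The genome build behind the probe sets is not given in the sources used here, so no coordinates are printed. For each of the 5656 genes the probe set with the highest mean over all arrays was used (315 genes have more than 1), and all genes were tested with no filter on dim signals.

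A linear model with a mean for each of the 21 combinations of strain and time (21 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation. Contrasts were the 6 heat times against the time before heat in each strain (each time, their mean, and a joint F test), the strain differences before heat and averaged over the 7 times, and the strain differences in heat response (each time, mean and joint F test). All tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a contrast and calls at an adjusted p under 0.05; for joint tests the direction is that of the largest difference. The design, the gene lists, the named-gene rule and the first group of alternatives below were chosen before the data were examined.

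The rule for named genes took the deleted genes and the auxotrophic markers LEU2, URA3, TRP1 and HIS4, then up to 10 rises and 10 falls of each comparison among called genes. For the heat response all 12 heated arrays had to lie on one side of both arrays before heat. For strain differences the arrays of the strains could not overlap, before heat or at 6 or more of the 7 times. For differences in heat response it took the 20 genes of smallest p in the joint test, and for each gene list up to 4 members of smallest p. The text names some of these genes and leaves others out.

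37 gene lists of yeast pathways, complexes, mating types and stress responses, fixed from general knowledge, were tested with camera at a preset correlation of 0.01, with camera and an estimated correlation, and with fry, each adjusted over the 37 lists of a contrast. Members were also counted with the adjustment made over the list alone. The report describes the lists it names and leaves out the others.

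The tests were tried on simulated data with 200 of 5656 genes changed. For the strain difference over all times 62.7%, 95.5% and 100% of genes changed by 0.5, 1 and 2 (log2) were called, with 11 false calls. Before heat the shares were 1.49%, 31.3% and 92.4% (4 false calls), for the mean heat response 5.97%, 61.2% and 97% (5 false calls), and for the joint test of a difference in heat response 1.49%, 1.49% and 62.1% (5 false calls). A list of 30 genes raised by 0.5 was called and 0 of 36 unchanged lists were. In these simulations genes and arrays varied independently, and the lists held random genes. The measured arrays of a strain's replicate course had a block correlation of 0.317, and genes of a real list can vary together. These false calls therefore do not give the error rates for the measured arrays or lists.

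Replicate numbers come from the labels and occur in every group. Deviations of same-numbered arrays from their group means were positively correlated in 210 of 210 combinations of groups over all non-control probe sets (lowest 0.130, median 0.524), and above 0.1 in 209 of 210 over the tested genes (lowest 0.067, median 0.412). The numbers were therefore treated as pairing the arrays, and fits with the replicate number as a block, within each strain or across strains, were set beside the design without it.

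The alternatives were median centring, cyclic loess and centring on the bacterial hybridisation controls, leaving out the dimmest 25% of genes, an adjusted p under 0.01, a trend with robust moderation, array weights, the mean of a gene's probe sets, all probe sets tested singly, replicate blocks, a random block of strain and replicate number, only the groups compared, each array left out in turn, and lists without probe sets shared between similar sequences. Added after the data had been seen were the mean of each strain's replicate course as 1 sample (with and without a block), a random course block beside the replicate block, each replicate number alone, the genes without non-coding and mitochondrially encoded ones, and the arrays without the double deletion's 10 min replicate 2, which had the largest 3' to 5' difference of the SRB4 control. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets with several genes or none were left out of the comparisons of genes.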

Results

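Gene expression was measured on 42 single-colour Affymetrix yeast arrays, each hybridised with biotin-labelled total RNA from Saccharomyces cerevisiae in log phase in YPD, a rich glucose medium. A parental strain was compared with a strain lacking DPL1, the lyase that breaks down phosphorylated sphingoid bases, the long-chain backbones of sphingolipids. The third strain, called the double deletion here, lacked LCB4 and LCB5, the kinases that phosphorylate those bases. Each strain was sampled before heat and after 5, 10, 15, 20, 25 and 30 min at 39 C, with 2 arrays at each of the 21 combinations of strain and time. The design asks how transcript levels follow heat in each strain, and whether either deletion changes those levels or their response to heat. Array medians lay between 5.61 and 5.80 (log2), and the arrays of a group correlated at 0.942 to 0.980 across genes, which are not independent replicates. The number of arrays limits the precision: the median SE was 0.31 for a strain difference at a single time and 0.12 for one averaged over the 7 times. Nothing says that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

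Control signals and non-coding transcripts differed between the arrays numbered 1 and those numbered 2. The 18S ribosomal RNA control averaged 13.1 ± 0.15 (SD, n = 21) in replicate 1 and 7.05 ± 2.70 in replicate 2. The SRB4 control read higher at its 3' than at its 5' end by 0.52 ± 0.27 and 1.97 ± 0.54 (log2) in these replicates. In replicate 2, 85 of 91 tRNA genes, 43 of 57 snoRNA genes and 15 of 19 mitochondrially encoded genes were lower. COB, apocytochrome b, was at -3.55 and ATP6, an ATP synthase subunit, at -3.02. Among 5467 protein-coding genes 2197 were higher and 678 lower in replicate 2. By strain, the 25S control averaged 12.2 in the DPL1 deletion, 11.5 in the parental strain and 10.5 in the double deletion. The SRB4 difference averaged 0.99, 1.22 and 1.51 in that order. An unannotated probe set that read 11.8 or more in the 28 deletion arrays and 4.27 or less in 13 parental arrays read 8.15 in the parental replicate 1 before heat. That array is 1 of the 2 behind the parental values before heat. Leaving out either of these 2 arrays lowered the number of genes called in the parental heat response at any time. That fall therefore does not single out this array. Before heat in the double deletion, more genes were called without this array and fewer without the other. In such fits the lone array left is assumed to vary like the other groups.

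The deleted genes were examined first. DPL1 (YDR294C) averaged 3.37 ± 0.23 (SD, n = 2) before heat in its deletion strain, against 8.83 ± 0.16 in the parental strain and 8.78 ± 0.08 in the double deletion. LCB4 (YOR171C) stood at 2.70 ± 0.24 in the double deletion, against 5.28 ± 0.27 and 5.08 ± 0.35 in the parental strain and the DPL1 deletion. LCB5 (YLR260W) stood at 3.21 ± 0.39 against 5.25 ± 0.38 and 5.82 ± 0.44. Over all times the differences from the parental strain were -6.14 ± 0.12 (SE, n = 14 arrays a strain) for DPL1 in its deletion, -1.85 ± 0.10 for LCB4 and -3.99 ± 0.12 for LCB5 in the double deletion. Each passed the threshold (largest adjusted p 3.26e-13). Whether these probe sets lie within the deleted parts is not given in the sources used here. Where they do, the signal left in a deletion is background, and these values are lower bounds of the differences in size. Alpha-specific transcripts were high before heat in all 3 strains, with the pheromone gene MF(ALPHA)1 at 12.1 or 12.2, while STE2, the alpha-factor receptor of a cells, was at 2.73, 2.78 and 2.84. The auxotrophic markers LEU2, URA3 and TRP1 did not pass the test between strains over all times. HIS4, of histidine synthesis, was lower in the double deletion than in the parental strain by -0.91 ± 0.31 (adjusted p 0.0419). Its arrays overlapped between the strains, running from 6.90 to 9.70 in the parental strain and from 6.46 to 8.35 in the double deletion. The parental replicates lay far apart before heat (SD 1.13).

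**Figure D1:**
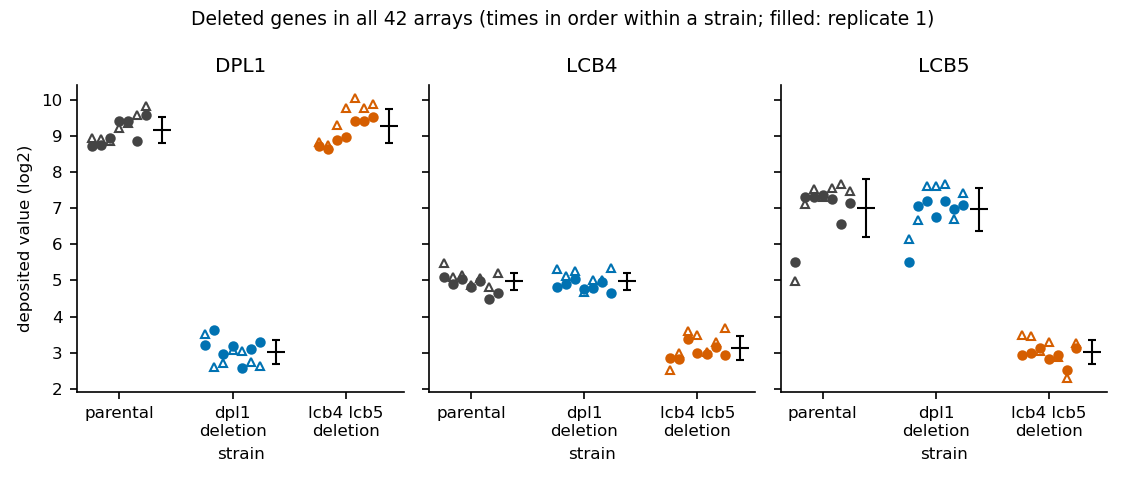
Expression (log2) of DPL1, LCB4 and LCB5 in each of the 42 arrays, by strain. Filled markers are replicate 1 and open triangles replicate 2. Bars give the mean and SD of the 14 arrays of a strain over all times. These SDs include changes with heat and are not the spread between replicates. DPL1 reached at most 3.63 in its deletion and at least 8.64 elsewhere, while LCB5 rose with heat in the parental strain and the DPL1 deletion.

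Heat raised stress-protection genes and lowered ribosome-production genes in the parental strain. Averaged over the 6 heat times against the time before heat (12 heated arrays and 2 before heat), HSP26, a small heat shock chaperone, rose by 6.17 ± 0.42 (log2, SE). HSP30, a plasma membrane stress protein, rose by 6.23 ± 0.84 and SSA4, an inducible Hsp70 chaperone, by 5.56 ± 0.37. The membrane-domain proteins YNL194C and FMP45 rose by 6.01 ± 0.45 and 5.40 ± 0.35. The cell wall protein SPI1 rose by 5.56 ± 0.34, the ribosome-associated protein TMA10 by 5.50 ± 0.45 and the hexose transporter HXT5 by 5.37 ± 0.39. The pentose phosphate enzyme SOL4 was higher by 5.34 ± 0.24 and PHM7 by 5.27 ± 0.30. In the other direction the nucleolar protein NSR1 fell by 4.17 ± 0.53. The pre-60S ribosome factors ARX1, RLP24, SSF1 and NOG1 changed by -3.92 ± 0.38, -3.75 ± 0.44, -3.71 ± 0.51 and -3.70 ± 0.55. RRP12, a factor of ribosomal RNA processing and export, was at -3.77 ± 0.52, the CTP synthase URA7 at -3.82 ± 0.41 and PHM6 at -3.86 ± 0.35. The adenine deaminase AAH1 was at -3.65 ± 0.46 and YAR068W, whose probe set is shared with similar sequences, at -3.68 ± 0.40. All 20 were picked among genes whose 12 heated arrays lay on the same side of both arrays before heat. Of 2621 genes called in the mean response 1685 met that rule. The 20 had adjusted p of 4.01e-06 or smaller.

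In the parental strain the number of called genes was highest at 20 min. Of 5656 genes limma called 801 at 5 min (392 higher, 409 lower), 1897 at 10 min (833, 1064), 2406 at 15 min (1125, 1281), 2427 at 20 min (1162, 1265), 2204 at 25 min (980, 1224) and 2053 at 30 min (1044, 1009). In the mean over heat 1233 genes rose and 1388 fell, 699 and 816 of them at least 2-fold. The joint test of all 6 times called 2194 genes. The mean signal of the hybridisation controls ran from 7.48 to 9.53 (log2) over the arrays, while array medians lay between 5.61 and 5.80. Centring on these controls carries their spread between arrays into every gene. Centring on the hybridisation controls shifted the median gene from -0.02 to 0.26. It turned the split of the mean response to 559 higher and 351 lower, or 61.4% higher against 47.0%, and left 776 genes at any time. At 5 min the count was 1249 with a replicate block within strains, 524 without the replicate 2 array before heat, and 432 and 513 without the 5 min arrays of replicate 1 and 2. Without that time's replicate 2 it was 1219 at 10 min and 1225 at 30 min, where the lone array is assumed to vary like the other groups.

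Chaperone, general stress and trehalose genes rose nearly as whole lists in the parental strain, and other stress lists in part. Of 31 genes in the list of heat shock chaperones 28 rose and none fell, or 30 adjusted over the list alone. Their median was 2.34 (adjusted p = 0.148 with an estimated correlation). The disaggregase HSP104 was at 3.31 ± 0.25 and the small heat shock protein HSP42 at 4.51 ± 0.35. All 32 Msn2/Msn4 general stress genes, targets of the paired stress activators of yeast, rose, 32 adjusted over the list alone. Their median was 3.66 (adjusted p = 0.0702 with an estimated correlation), with the catalase CTT1 at 4.85 ± 0.27, TFS1 at 3.99 ± 0.22 and MSC1 at 5.02 ± 0.28. All 20 genes of trehalose and glycogen metabolism rose, 20 adjusted over the list alone, with a median of 2.66 (adjusted p = 0.0829 with an estimated correlation). Among them were the trehalose phosphate phosphatase TPS2 (3.71 ± 0.23), the glycogen synthase GSY2 (3.97 ± 0.22) and the phosphoglucomutase PGM2 (4.76 ± 0.28). Among 33 genes of oxidative stress defence 18 rose and 3 fell, 18 and 3 adjusted over the list alone. Their median was 0.79 (adjusted p = 0.409 with an estimated correlation), and the peroxiredoxin TSA2 was at 3.62 ± 0.33 and the glutaredoxin GRX1 at 2.23 ± 0.21. Autophagy genes followed, with 20 of 28 up and 1 down, 20 and 1 adjusted over the list alone. Their median was 0.88 (adjusted p = 0.148 with an estimated correlation), with ATG8 at 2.48 ± 0.31. Of 36 proteasome genes 14 rose, 13 adjusted over the list alone. The proteasome median was 0.45 (adjusted p = 0.415 with an estimated correlation), with RPN4, the proteasome gene activator, at 1.89 ± 0.39. Of 23 genes of the unfolded protein response and ER folding 10 rose and 1 fell, 11 and 2 adjusted over the list alone. Their median was 0.43 (adjusted p = 0.415 with an estimated correlation), with the oxidase ERO1 at 2.05 ± 0.24 and the chaperone KAR2 at 1.42 ± 0.18.

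Genes for making ribosomes and proteins fell in the parental strain. Of 111 ribosome biogenesis genes 109 fell and none rose, 109 adjusted over the list alone. The median was -2.72 (adjusted p = 0.156 with an estimated correlation). The nucleolar proteins NOP7 and RRP1 were at -2.75 ± 0.23 and -3.01 ± 0.26 and the helicase DBP2 at -3.55 ± 0.30. Of 26 genes of RNA polymerase I and III 23 fell, 23 adjusted over the list alone, with a median of -1.63 (adjusted p = 0.148 with an estimated correlation) and RPA43 at -3.27 ± 0.34. Of 81 cytosolic ribosomal protein genes 79 fell, 80 adjusted over the list alone, with a median of -1.76 (adjusted p = 0.209 with an estimated correlation). RPL30 was at -1.53 ± 0.19. Several of these genes have probe sets shared with a near-identical copy and are uncertain as single genes. The ribosome biogenesis median was already -1.75 at 5 min, with 75 genes down. That of the ribosomal proteins was -0.34 with 1 gene down at 5 min, and -2.52 with 79 down at 20 min. Translation factors fell in 25 of 32 cases, 25 adjusted over the list alone, with a median of -1.42 (adjusted p = 0.138 with an estimated correlation). TIF4631, an eIF4G, was at -2.29 ± 0.26. The tRNA synthetases fell in 18 of 21, 18 adjusted over the list alone, with a median of -1.41 (adjusted p = 0.162 with an estimated correlation). ALA1, for alanine, was at -1.97 ± 0.21. Of 66 mitochondrial ribosomal protein genes 1 rose and 11 fell, 1 and 5 adjusted over the list alone. Their median was -0.31, and the list test was not passed (adjusted p 0.0676, and 0.0342 with the replicate block).

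Lists of cell-cycle, mating and nutrient genes held more falls than rises. Of 32 G1 and S phase genes 21 fell and none rose, 22 adjusted over the list alone. Their median was -0.99 (adjusted p = 0.148 with an estimated correlation). The G1 cyclins PCL1 and CLN2 were at -3.26 ± 0.25 and -2.52 ± 0.22, the ribonucleotide reductase subunit RNR1 at -3.18 ± 0.38 and the sliding clamp POL30 at -2.18 ± 0.21. Among 21 G2 and M phase genes 9 fell and 1 rose, 9 and 1 adjusted over the list alone. Their median was -0.55 (adjusted p = 0.453 with an estimated correlation), with the cyclin CLB1 at -2.18 ± 0.28. All 4 alpha-specific mating genes fell, 4 adjusted over the list alone. Their median was -2.69 (adjusted p = 0.156 with an estimated correlation), with the receptor STE3 at -3.14 ± 0.44 and the pheromone gene MF(ALPHA)2 at -2.87 ± 0.36. Of 68 amino acid synthesis genes 36 fell and 5 rose, 40 and 5 adjusted over the list alone. The median was -0.74 (adjusted p = 0.329 with an estimated correlation), with the isopropylmalate synthase LEU9 at -2.74 ± 0.26. Of 22 purine synthesis genes 13 fell and 1 rose, 13 and 1 adjusted over the list alone. The purine median was -1.43 (adjusted p = 0.317 with an estimated correlation), with GUA1 at -1.96 ± 0.26 and ADE16 at 1.58 ± 0.21. Of 16 phosphate starvation genes 13 fell and 2 rose, 13 and 2 adjusted over the list alone. Their median was -1.19 (adjusted p = 0.317 with an estimated correlation), with the acid phosphatase PHO3 at -3.14 ± 0.39 and PHM8, a phosphatase of nucleotide turnover, at 2.97 ± 0.23. Of 28 genes of methionine and sulfur assimilation 12 fell and 2 rose, 12 and 2 adjusted over the list alone. Their median was -0.54 (adjusted p = 0.454 with an estimated correlation). The S-adenosylmethionine synthetase SAM1 was at -3.57 ± 0.47, the S-methylmethionine permease MMP1 at -1.95 ± 0.25 and MET17, the sulfhydrylase that makes homocysteine, at -1.34 ± 0.24.

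Lipid and energy genes moved in both directions. Of 43 sphingolipid genes 11 rose and 11 fell, 11 and 13 adjusted over the list alone. The list did not pass the test (adjusted p 0.966). Its median was -0.02 and its mean 0.07, and the median stood at 0.03 after median centring and 0.26 after hybridisation-control centring. In that list LCB5 rose by 2.05 ± 0.24, the ceramidase YDC1 by 1.88 ± 0.18 and the kinase YPK2 by 2.15 ± 0.21, and the acyl-CoA synthetase FAA4 fell by 1.98 ± 0.23. Of 27 ergosterol genes 15 fell and 2 rose, 15 and 2 adjusted over the list alone. Their median was -0.59 (adjusted p = 0.415 with an estimated correlation), with the desaturase ERG3 at -1.94 ± 0.25. Of 7 fatty acid synthesis genes 3 fell, 4 adjusted over the list alone, with a median of -0.61 (adjusted p = 0.415 with an estimated correlation). The synthase subunit FAS1 was at -1.23 ± 0.17 and the desaturase OLE1 at -1.74 ± 0.25. Peroxisome and fatty acid oxidation genes rose in 11 of 27 cases, 11 adjusted over the list alone, with a median of 0.46 (adjusted p = 0.317 with an estimated correlation). The carnitine carrier CRC1 was at 2.43 ± 0.18 and the thiolase POT1 at 1.89 ± 0.30. Of 25 TCA and glyoxylate cycle genes 13 rose, 15 adjusted over the list alone. Their median was 0.77 (adjusted p = 0.317 with an estimated correlation), with the citrate synthase CIT1 at 1.62 ± 0.27. Of 44 respiratory chain and ATP synthase genes 11 rose and 1 fell, 11 and 0 adjusted over the list alone. Their median was 0.14 (adjusted p = 0.636 with an estimated correlation), with the cytochrome c isoform CYC7 at 3.48 ± 0.33 and the NADH dehydrogenase NDE2 at 3.02 ± 0.37. Of 23 iron uptake genes 12 rose and 2 fell, 13 and 2 adjusted over the list alone. Their median was 0.54 (adjusted p = 0.415 with an estimated correlation), with the cell wall siderophore protein FIT2 at 3.32 ± 0.43. Cell wall genes split into 14 up and 10 down of 45, 14 and 10 adjusted over the list alone, and did not pass the list test (adjusted p 0.596). Their median was -0.12, which became 0.16 after hybridisation-control centring, and their mean 0.15. The cell wall protein PIR3 rose by 3.30 ± 0.36 and SCW10 fell by 3.16 ± 0.34. Of 37 lists camera called 26 in the mean heat response, among them each list described here except the 3 said not to pass, and fry called 30. With camera 0 were called with an estimated correlation, where 0.0702 was the smallest adjusted p. After hybridisation-control centring FAS1, OLE1, RPL30 and MET17 were no longer called.

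**Figure D2:**
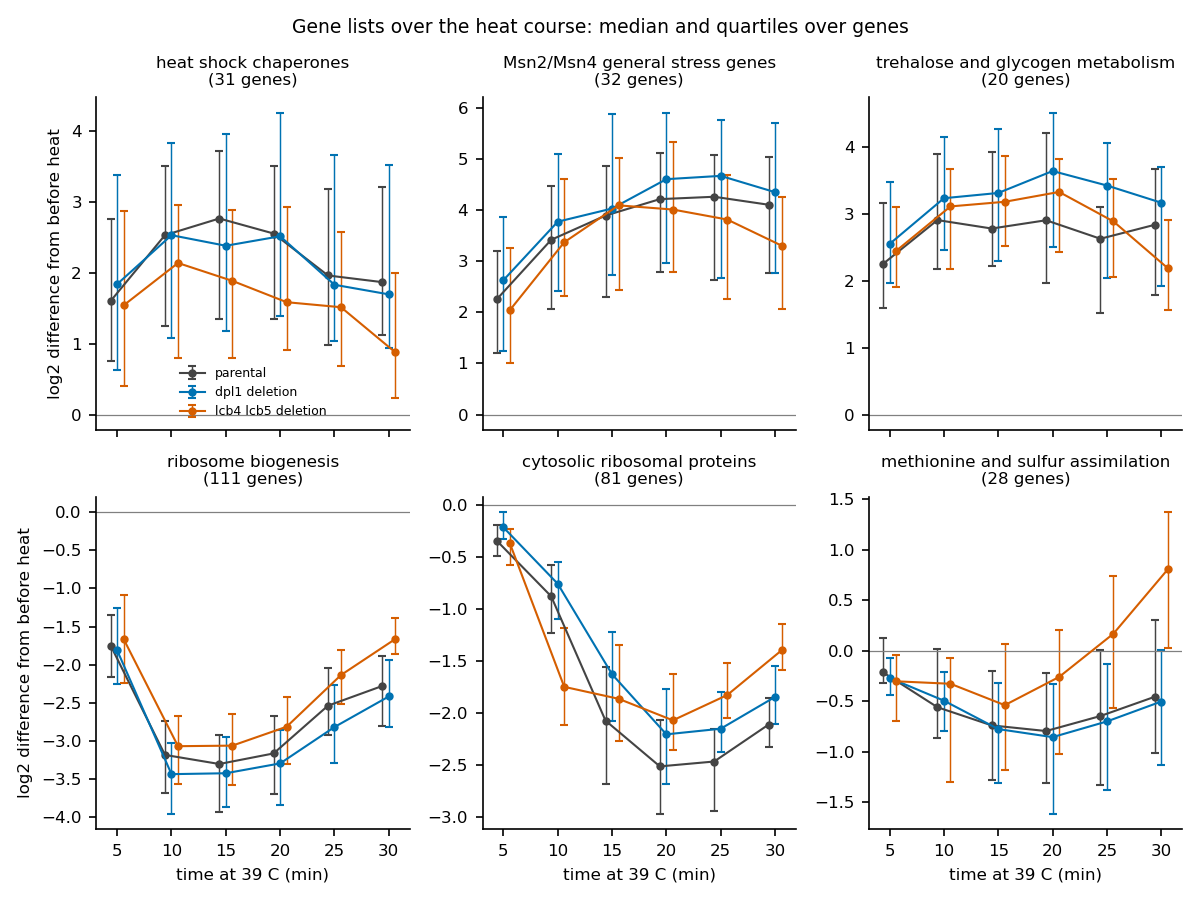
Median log2 difference from the time before heat over the measured genes of 6 gene lists, against time at 39 C (min), in the 3 strains; bars span the quartiles of the genes. Ribosome biogenesis in the parental strain was at -1.75 at 5 min and -2.28 at 30 min, cytosolic ribosomal proteins at -0.34 and -2.11, and Msn2/Msn4 general stress genes at 2.26 and 4.11.

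Both deletion strains raised and lowered many of these genes with heat. In the DPL1 deletion HSP26 rose by 7.65 ± 0.42, HSP30 by 7.20 ± 0.84, SSA4 by 6.40 ± 0.37, the catalase CTT1 by 6.03 ± 0.27 and EGO4 by 6.07 ± 0.34. In this strain NSR1 fell by 4.43 ± 0.53, AAH1 by 4.14 ± 0.46 and ECM1, a 60S export factor, by 3.88 ± 0.31. In the double deletion SPG4 rose by 5.98 ± 0.41, YNL194C by 5.94 ± 0.45, HSP30 by 5.82 ± 0.84 and the aldehyde dehydrogenase ALD3 by 5.37 ± 0.39. There AAH1 fell by 3.72 ± 0.46, the endonuclease HO by 3.70 ± 0.24, the helicase DBP2 by 3.63 ± 0.30 and RNR1 by 3.36 ± 0.38. The mean response held 1167 rises and 1504 falls in the DPL1 deletion and 1079 and 1426 in the double deletion, with 2181 and 2204 genes called at any time. The parental strain and the DPL1 deletion shared 1020 rises and 1257 falls, where independent lists would share 254 and 369. Between the parental strain and the double deletion 943 and 1197 were shared (235 and 350 for independent lists). No gene was called in opposite directions between these strains. Centring on the hybridisation controls turned the splits to 535 higher and 390 lower in the DPL1 deletion (57.8% higher against 43.7%) and 407 and 305 in the double deletion (57.2% against 43.1%).

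Members of several of these lists were called in the deletion strains too, and the counts are given without a test of the difference between strains. All 20 trehalose and glycogen genes rose in both deletions, 20 adjusted over the list alone in each. Their medians were 3.21 in the DPL1 deletion (adjusted p = 0.0593 with an estimated correlation) and 2.87 in the double deletion, where the call held with an estimated correlation (adjusted p 0.0479). The Msn2/Msn4 list rose in 32 of 32 genes in the DPL1 deletion, 32 adjusted over the list alone, with a median of 3.73 (adjusted p = 0.0516 with an estimated correlation). In the double deletion 31 rose, 31 adjusted over the list alone, with a median of 3.61, and the call held with an estimated correlation (adjusted p 0.0479). Chaperones rose in 28 of 31 cases in the DPL1 deletion, 30 adjusted over the list alone, with a median of 2.22 (adjusted p = 0.146 with an estimated correlation). They rose in 24 in the double deletion, 24 adjusted over the list alone, with a median of 1.60 (adjusted p = 0.191 with an estimated correlation). Ribosome biogenesis fell in 109 of 111 genes in each deletion, 109 adjusted over the list alone in each. The medians were -2.90 (adjusted p = 0.197 with an estimated correlation) and -2.44 (adjusted p = 0.191 with an estimated correlation). Of 81 cytosolic ribosomal protein genes 75 fell in the DPL1 deletion, 78 adjusted over the list alone, with a median of -1.46 (adjusted p = 0.336 with an estimated correlation). In the double deletion 78 fell, 80 adjusted over the list alone, with a median of -1.60 (adjusted p = 0.267 with an estimated correlation). Methionine and sulfur genes fell in 15 of 28 cases in the DPL1 deletion, 16 adjusted over the list alone, with 1 rise by both counts. Their median was -0.62 (adjusted p = 0.472 with an estimated correlation). In the double deletion 6 rose and 9 fell, 6 and 9 adjusted over the list alone, and the list was not called (adjusted p 0.647). Its median was -0.08, and 0.16 after hybridisation-control centring. The cystathionine lyase STR3 rose by 1.52 ± 0.39 there, with 1.24 and no call without that strain's replicate 2 before heat.

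The DPL1 deletion strain differed from the parental strain in DPL1 alone by the test over all 5656 genes. Of 2771 probe sets with several genes or none listed, 2 were higher over all times, the unannotated one given above and 3954_at, by 0.76 ± 0.09 (adjusted p 7.89e-05). DPL1 was lower by -5.46 ± 0.31 before heat (adjusted p 5.56e-12) and by -6.14 ± 0.12 over all times (adjusted p 1.23e-23). In each of these comparisons limma called 1 of 5656 genes (131 and 213 at an unadjusted p under 0.05). The count over all times was 5 with the replicate block within strains, where SNO1, USO1, YCT1 and YJR079W joined DPL1. It was DPL1 alone with the block across strains, and with the mean of each course as 1 sample beside a replicate block. Within replicate number 1 alone it was 16 (10 higher, 6 lower), and within number 2 alone it was 2 (with YJR079W). Before heat it was 6 without the DPL1 deletion's replicate 2 (FRE1, AAC3, DSF2, KAR4 and SLM5 beside DPL1). It was 2 without the parental replicate 1 (with YPT6) and 2 without the parental replicate 2 (with HSP26). No gene differed in its response to heat at any time by limma's joint test (27 at an unadjusted p under 0.05), nor in the mean response (111 unadjusted). In the joint test HSP26 was called without the parental replicate 2 before heat (count of 1), and the ribosomal RNA gene RDN18-1 after centring on the hybridisation controls (count of 1). At single times the count was also 0, with 28 to 214 genes unadjusted. The genes that joined under these alternatives and the unannotated probe sets were chosen after their values were seen.

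Several stress and ribosome lists had small medians in this comparison, with 0 members called over all genes and none called with an estimated correlation or by fry. Before heat the Msn2/Msn4 list had a median of -0.30, with 0 adjusted over the list alone (adjusted p = 0.693 with an estimated correlation). Trehalose and glycogen metabolism had a median of -0.27 and ribosome biogenesis of 0.30, each with 0 adjusted over the list alone (adjusted p = 0.949 with an estimated correlation for both). Over all times cytosolic ribosomal proteins had a median of 0.25, with 0 adjusted over the list alone (adjusted p = 0.614 with an estimated correlation). Ribosome biogenesis stood at 0.20, with 0 adjusted over the list alone (adjusted p = 0.633 with an estimated correlation), and at -0.01 after hybridisation-control centring. That centring moved the median gene from 0.00 to -0.21 over all times.

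Before heat, 4 genes were higher and 2 lower in the double deletion than in the parental strain. CRG1, a lipid methyltransferase whose probe set is shared with similar sequences, was higher by 1.97 ± 0.38 (SE, n = 2 arrays a strain; adjusted p 0.0267). The stress-induced glucan synthase GSC2 was higher by 1.75 ± 0.35 and KDX1, a relative of the cell wall kinase Slt2, by 1.45 ± 0.29 (adjusted p 0.0403 for both). NFG1 was higher by 1.35 ± 0.25 (adjusted p 0.0202). LCB4 and LCB5 were lower by -2.58 ± 0.25 and -2.04 ± 0.32 (adjusted p 1.11e-06 and 0.00298). This made 6 calls in all (250 genes unadjusted). Of 45 cell wall genes 2 were higher, 8 adjusted over the list alone, with a median of 0.23 (adjusted p = 0.658 with an estimated correlation). The 44 respiratory chain genes had a median of -0.50 with 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.781 with an estimated correlation). The 6 calls became 22 with a replicate block within strains and 10 across strains, and 0 after hybridisation-control centring or with the 4 compared arrays alone. They became 9 after cyclic loess (7 higher and 2 lower, 77.8% higher against 66.7%) and 3 after median centring (1 and 2, 33.3%). Without the parental replicates 1 and 2 the counts were 24 and 2, and without replicate 1 or 2 of the double deletion 3. LCB4 was called whichever of the 4 arrays was left out and GSC2 was lost without any 1 of them. LCB5 was lost without the double deletion's replicate 1, NFG1 without that array or the parental replicate 2, and CRG1 and KDX1 without any 1 of the 3 arrays other than the parental replicate 1.

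Over all times, many genes were called as different in the double deletion from the parental strain, by small amounts. The SEs take the 14 arrays of a strain as independent. Those arrays form 2 courses with a block correlation of 0.317, so the SEs leave out the spread between courses. KDX1 was higher by 1.66 ± 0.11 (SE, n = 14 arrays a strain), the glucose transporter HXT1 by 1.46 ± 0.29, the putative reductase YPL088W by 1.34 ± 0.17 and the drug exporter PDR5 by 1.30 ± 0.12. The cell wall proteins PIR3 and PST1 were higher by 1.11 ± 0.18 and 1.08 ± 0.16. CRG1 stood at 1.07 ± 0.14, the pheromone-regulated PRM5 at 1.04 ± 0.19 and the nucleolar proteins UTP14 and NOP56 at 1.03 ± 0.23 and 0.98 ± 0.28. Beside LCB5 and LCB4, ATG41, of autophagy, was lower by -1.77 ± 0.35, INH1, the inhibitor of the mitochondrial ATP synthase, by -1.22 ± 0.23, and the cytochrome oxidase subunits COX5A and COX9 by -1.09 ± 0.24 and -0.89 ± 0.27. The coactivator MBF1 was lower by -0.90 ± 0.21 and the snoRNA SNR71 by -1.04 ± 0.20. SUP16, a tRNA gene, and the non-coding YNCJ0001C, both on shared probe sets, were lower by -1.44 ± 0.25 and -1.34 ± 0.22. In the DPL1 deletion KDX1, HXT1, PDR5 and INH1 differed from the parental strain by 0.06, 0.06, 0.13 and -0.03, none past the threshold. PDR5 stood at 0.75 in the mean of its probe sets and was not called there. COX9 was lost without the parental 15 min replicate 1 (-0.76) or the double deletion's 20 min replicate 2 (-0.74), and PRM5, UTP14 and NOP56 after hybridisation-control centring.

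In all, limma called 1104 of 5656 genes over all times in the double deletion, 721 higher and 383 lower, of which 10 and 53 differed by at least 2-fold (1896 at an unadjusted p under 0.05). In 201 of them the strains' arrays did not overlap at 6 or more of the 7 times, and 1101 had the same sign in both replicates. The calls were made on these same replicates, so this agreement in sign is largely set by the calls. Over all 5656 genes the differences in the 2 replicates correlated at 0.579. With the replicate block the count was 1919 within strains and 1796 across strains, and within replicate number 1 and 2 alone it was 1224 and 1117. The block within strains takes the spread between a strain's 2 courses out of the error. A single replicate number holds 1 course a strain. The counts of 1919, 1224 and 1117 are therefore not weighed against the spread between courses. The count was 21 (12 higher, 9 lower) with each strain's replicate course as a random block. That fit kept KDX1, YPL088W, PDR5, PST1, CRG1, GSC2, LCB4 and LCB5 of the genes named for this comparison. With the mean of each course as 1 sample the count was 1 (LCB5). With those means and a replicate block it was 145, 53 higher and 92 lower. Median centring gave 476 higher and 508 lower (48.4% higher against 65.3%) and hybridisation-control centring 8 and 104 (7.14%). Of the 2771 probe sets with several genes or none listed, 153 were called over all times in the double deletion, 53 higher and 100 lower.

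**Figure D3:**
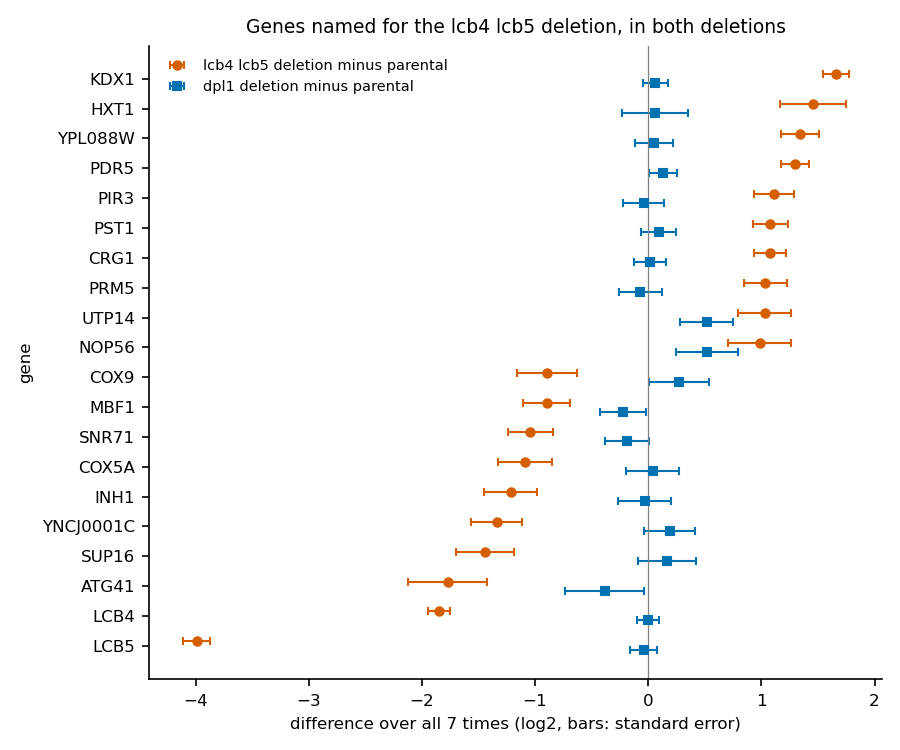
Log2 difference from the parental strain over all 7 times for 20 genes, in the double deletion and in the DPL1 deletion, with bars of 1 SE (14 arrays a strain). The SEs take the 14 arrays of a strain as independent and leave out the spread between replicate courses. KDX1 was at 1.66 in the double deletion and 0.06 in the DPL1 deletion, and LCB5 at -3.99 and -0.04.

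Over all times, part of the ribosome-production and cell wall genes were called higher, and part of the respiratory genes lower, in the double deletion. The medians of the ribosome biogenesis, polymerase, respiratory and cell wall lists were 0.49, 0.26, -0.47 and 0.18 after median centring, and 0.43, 0.20, -0.53 and 0.12 after hybridisation-control centring. Of 111 ribosome biogenesis genes 61 were higher and 0 lower, 84 and 1 adjusted over the list alone, with a median of 0.55 (adjusted p = 0.854 with an estimated correlation). The export factor NUG1 was at 0.90 ± 0.16 and the methyltransferase SPB1 at 0.68 ± 0.13. Of 26 RNA polymerase I and III genes 9 were higher and 1 lower, 15 and 1 adjusted over the list alone, with a median of 0.32 (adjusted p = 0.854 with an estimated correlation). The large polymerase III subunits RET1 and RPO31 were at 0.65 ± 0.11 and 0.58 ± 0.10. Of 44 respiratory chain and ATP synthase genes 21 were lower and 0 higher, 27 and 1 adjusted over the list alone. Their median was -0.41 (adjusted p = 0.854 with an estimated correlation), with the ATP synthase subunit ATP5 at -0.65 ± 0.11 and COX6 at -0.80 ± 0.13. Of 45 cell wall genes 19 were higher and 2 lower, 19 and 2 adjusted over the list alone, with a median of 0.24 (adjusted p = 0.854 with an estimated correlation). The glucanase EXG1 was at 0.82 ± 0.11, DFG5 at 0.62 ± 0.08 and GSC2 at 0.96 ± 0.13. Iron uptake genes were lower in 7 of 23 cases and higher in 1, 8 and 2 adjusted over the list alone. Their median was -0.17 (adjusted p = 0.854 with an estimated correlation), with the siderophore transporter ENB1 at -0.67 ± 0.11 and FIT2 at -1.20 ± 0.21. The chaperone list also holds genes of other roles, such as the coactivator MBF1. Members of that list were lower in 4 of 31 cases, 4 adjusted over the list alone (median -0.16, adjusted p = 0.854 with an estimated correlation). These were MBF1 (-0.90), APJ1 (-0.70), CUR1 (-0.68) and HCH1 (-0.41). Signals of a-specific genes were lower in 4 of 7 cases, 4 adjusted over the list alone, with a median of -0.28. These were ASG7 (-0.42), MFA2 (-0.41), MFA1 (-0.32) and STE2 (-0.28). How far the signals of these probe sets lie above background was not measured here, but they were among the dimmer ones. Averaged over the arrays before heat, ASG7 and STE2 lay above only 2.19% and 2.49% of the tested genes. MFA1 and MFA2 lay above 11.2% and 23.9%, and the 4 alpha-specific genes above 80.6% to 99.0%. The differences of these a-specific genes are therefore not read as changes in transcript level. The a-specific list's call (adjusted p 0.0433) ended with the replicate block (0.0926), without shared probe sets (0.125) and with an estimated correlation (adjusted p = 0.854). Hexose transport genes did not pass the list test (adjusted p 0.512), with 5 higher and 1 lower of 17, 6 and 3 adjusted over the list alone. The low-affinity transporter HXT3 was at 0.94 ± 0.18. Sphingolipid genes did not either (adjusted p 0.188), with 6 higher and 6 lower of 43, 8 and 7 adjusted over the list alone. The kinase YPK2 was at 0.67 ± 0.10. By fry the lists of ribosome biogenesis, RNA polymerases, respiration, cell wall and iron uptake were called as well, and pheromone response too (adjusted p 0.000844 to 0.0318). Of the single genes named here GSC2 alone was called with courses as random blocks, and FIT2 alone after hybridisation-control centring. GSC2 stood at 0.47 in the mean of its probe sets and was not called there. Beside these, 47 of 91 tRNA genes were lower in the double deletion (median -1.02), the strain with the lowest mean 25S control signal.

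The response to heat differed between the double deletion and the parental strain in MET17. In the parental strain MET17 went from 10.1 ± 0.05 (SD, n = 2) before heat to 8.43 ± 0.01 at 15 min and 8.74 ± 0.74 at 30 min. In the double deletion it went from 9.82 ± 0.08 to 8.27 ± 0.08 and 10.9 ± 0.40. It was the single gene called by limma's joint test of all times (adjusted p 0.0114; 171 genes unadjusted). Over the alternatives the adjusted p ran from 0.00153 to 1.00. The call was lost after cyclic loess (0.0865) or hybridisation-control centring, with array weights (0.0564), with the compared groups alone (0.25), and also without the parental 30 min replicate 2 (0.0668) or the double deletion's 30 min replicate 1 (0.127). LCB5, deleted in this strain, rose in the parental strain by 2.05 ± 0.24 and stood at -0.22 ± 0.24 in the double deletion. The difference in mean response was -2.27 ± 0.35 (adjusted p 0.00376), the single call of that contrast (171 unadjusted), and it is set by the deletion of the gene. With the replicate block across strains LCB5 joined MET17 in the joint test (adjusted p 0.0396, in a range of 0.0207 to 1). The count was also 2 without parental replicate 1 before heat (HSP26 beside MET17), at 5 min (MET6) or at 25 min (LCB5), and without the double deletion's replicate 1 at 25 min (MET2) or replicate 2 at 30 min (MMP1).

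At 30 min the genes of methionine and sulfur assimilation stood higher relative to their starting levels in the double deletion than in the parental strain. The median difference in response over 28 genes was 1.23, positive in 26 of them, with 0 called over all genes and 16 adjusted over the list alone. The list held with an estimated correlation (adjusted p 0.00355) and by fry (0.00626). It was the only one of 37 lists at 30 min to hold with an estimated correlation. Adjusted over all 666 tests of 37 lists at 6 heat times in 3 strain pairs, that p was 0.0334. Among the alternatives run the call ended only under hybridisation-control centring (median 1.44, adjusted p 0.170, in a range of 0.00225 to 0.170). The median by time was -0.21, -0.17, 0.12, 0.37, 0.66 and 1.23 from 5 to 30 min, with 2 genes adjusted over the list alone at 25 min (adjusted p = 0.182 with an estimated correlation). In the double deletion MET2, the homoserine acetyltransferase, read 5.34 ± 0.18 before heat and 8.15 ± 0.24 at 30 min, against 5.66 ± 0.08 and 6.08 ± 0.71 in the parental strain. STR3 read 4.60 ± 0.40 and 8.94 ± 1.14 against 5.31 ± 0.33 and 6.66 ± 0.96. The methionine permease MUP1 read 8.32 ± 0.18 and 10.1 ± 0.36 against 8.26 ± 0.34 and 8.56 ± 0.58, and the methionine synthase MET6 read 7.83 ± 0.04 and 9.92 ± 0.13 against 9.09 ± 1.42 and 8.64 ± 0.14. None of these 4 passed the joint test over all genes (adjusted p 0.197 for MET2, 0.477 for STR3 and MET6, and 0.867 for MUP1). In the mean response 7 lists were called and 0 with an estimated correlation or by fry. Chaperones had a median of -0.53, with 0 members called and 0 adjusted over the list alone (adjusted p = 0.478 with an estimated correlation). Ribosome biogenesis had 0.33, with 0 and 0 (adjusted p = 0.73 with an estimated correlation).

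**Figure D4:**
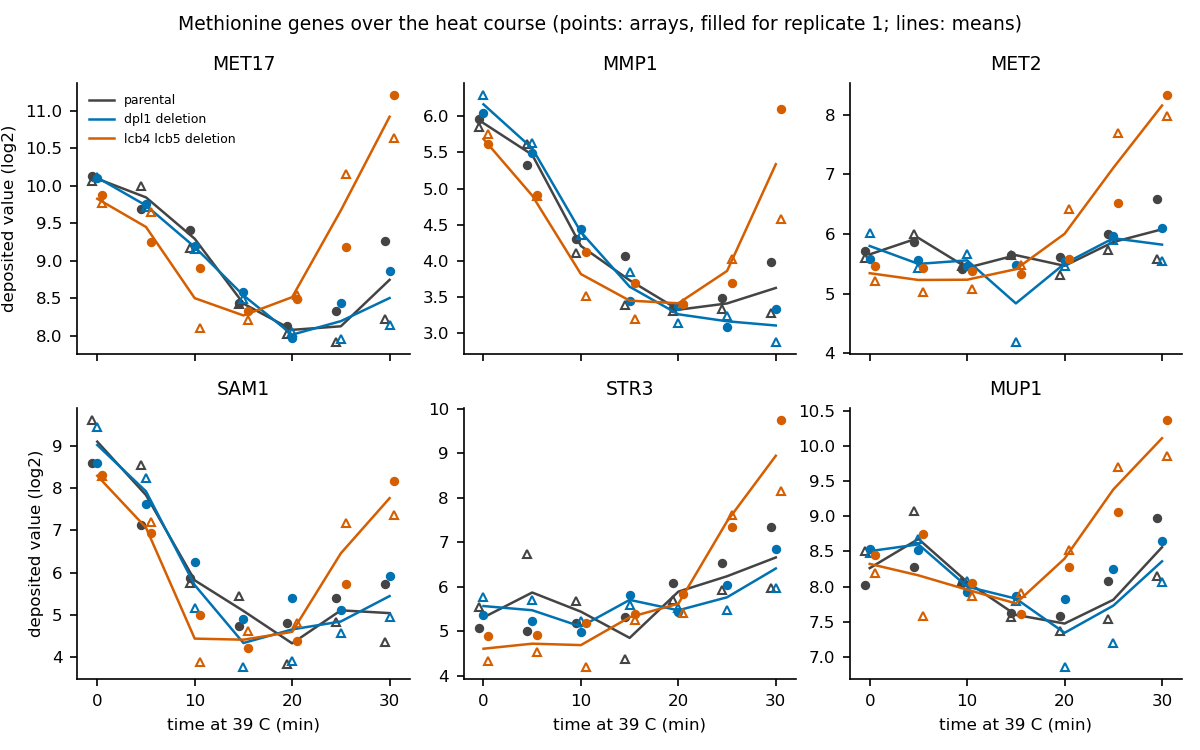
Expression (log2) of MET17, MMP1, MET2, SAM1, STR3 and MUP1 in each array against time at 39 C (min) in the 3 strains, with filled markers for replicate 1, open triangles for replicate 2 and lines through the means of 2 arrays. At 30 min MET17 averaged 10.9 in the double deletion, 8.74 in the parental strain and 8.50 in the DPL1 deletion.

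The deletion strains were also set against each other, in comparisons that share the double deletion's arrays with those above. Before heat, with positive values higher in the DPL1 deletion, LCB5 and LCB4 were at 2.61 ± 0.32 and 2.38 ± 0.25 and DPL1 at -5.41 ± 0.31. The cell wall protein CWP1 was at -2.41 ± 0.48, CRG1 at -2.03 ± 0.38, KDX1 at -1.75 ± 0.29, the cell wall protease YPS3 at -1.43 ± 0.29 and NFG1 at -1.18 ± 0.25. These were the 8 calls (185 genes unadjusted; largest adjusted p 0.0436). With the replicate block there were 26 within strains and 15 across strains, and with hybridisation-control centring 1. Without replicate 1 or 2 of the double deletion there were 4, and without replicate 2 of the DPL1 deletion 12. DPL1, LCB4 and LCB5 were called whichever of the 4 arrays was left out, and each of the others was lost without at least 1 of them. Over all times KDX1 was at -1.60 ± 0.11, HXT1 at -1.40 ± 0.29, YPL088W at -1.29 ± 0.17, PIR3 at -1.15 ± 0.18, PRM5 at -1.10 ± 0.19 and the ferric reductase relative FRE7 at -1.01 ± 0.15. The tRNA gene EMT5, on a shared probe set, was at 2.26 ± 0.25. In all 230 genes were higher and 495 lower in the DPL1 deletion, 60 and 10 of them by at least 2-fold. Of 44 respiratory chain genes 23 were higher, 30 adjusted over the list alone, with a median of 0.45 (adjusted p = 0.506 with an estimated correlation). The cytochrome oxidase subunits COX4 and COX6 were at 1.08 ± 0.20 and 0.82 ± 0.13. Of 45 cell wall genes 16 were lower, 21 adjusted over the list alone with 1 higher, and the median was -0.25 (adjusted p = 0.82 with an estimated correlation). Of 21 pheromone response genes 7 were lower, 10 adjusted over the list alone. Their median was -0.24 (adjusted p = 0.506 with an estimated correlation), with the G protein subunit GPA1 at -0.54 ± 0.13. Of 111 ribosome biogenesis genes 11 were lower and 1 higher, 8 and 0 adjusted over the list alone, with a median of -0.36 (adjusted p = 0.82 with an estimated correlation). The replicate block within strains takes the spread between a strain's courses out of the error here too. The 725 calls became 1599 and 1430 with the block within and across strains, and 28 with courses as random blocks. They became 261 higher and 341 lower after median centring (43.4% higher against 31.7%), 74 and 20 after hybridisation-control centring (78.7%), 79 and 22 with course means and a replicate block, and 482 and 448 without the double deletion's replicate 2 at 20 and 25 min. HXT1, PIR3, PRM5, COX4 and COX6 were lost with courses as random blocks, COX6 after hybridisation-control centring, and HXT1 (-0.63) within replicate number 1 alone.

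The heat responses of the deletion strains differed in MET17 and MMP1 by limma's joint test (adjusted p 0.00600 and 0.0372; 145 genes unadjusted). At 30 min the difference in response, with negative values lower in the DPL1 deletion, was -2.70 ± 0.45 for MET17, -2.71 ± 0.46 for MMP1 and -2.79 ± 0.52 for MET2 (adjusted p 0.0117, 0.0117 and 0.0237). MMP1 read 6.17 ± 0.18 before heat and 3.11 ± 0.32 at 30 min in the DPL1 deletion, against 5.69 ± 0.10 and 5.34 ± 1.08 in the double deletion. All 28 methionine and sulfur genes had a negative difference at 30 min, with a median of -1.26, 3 called over all genes and 17 lower adjusted over the list alone. The list held with an estimated correlation (adjusted p 0.00371) but not after hybridisation-control centring (median -1.82, adjusted p 0.198, in a range of 0.0025 to 0.198). Between the DPL1 deletion and the parental strain the list's median at 30 min was -0.17, with 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.988 with an estimated correlation). The joint count of 2 became 5 with the replicate block within strains, where MXR1, SAM2 and YNR065C joined, 6 across strains, with MHT1 too, and 0 without the 30 min replicate 2 of the DPL1 deletion or replicate 1 of the double deletion. It was 4 without the double deletion's 10 min replicate 1 (WHI5 and YGR240C-A joined, chosen after their values were seen) and 1 without any of 20 other single arrays, where MMP1 was the gene lost. No gene was called in the mean response (172 unadjusted).

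By limma no gene was called in opposite directions by the deletions over all times, but the DPL1 deletion had 1 call, DPL1 itself, and independent lists would give 0.128 such genes, so this count says little. At an unadjusted p under 0.05 there were 112 genes with the same direction and 3 with opposite ones, where independent lists would give 33.7 and 37.7. Both comparisons used the same parental arrays, and the differences correlated at 0.267 across genes, with a covariance of 0.0135 and the same sign in 63.3% of genes. In 100 simulations of unchanged groups against shared controls the correlation had a median of 0.498. The covariance had a median of 0.0108 and a highest value of 0.0129, and the share of genes with the same sign a median of 66.6%.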

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

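The tests on single arrays, on RNA quality for the methionine genes, on course means and on the random course block beside the replicate block were chosen only after the results they measure were seen, while the random course block alone was planned.

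MET17 differed in its heat response between the double deletion and the parental strain (joint test, adjusted p 0.0114) and between the deletion strains (adjusted p 0.00600), where MMP1 also differed (adjusted p 0.0372). LCB5, deleted in the double deletion, differed from the parental strain in its mean response by -2.27 ± 0.35 (adjusted p 0.00376) and at 25 min by -2.65 ± 0.45 (adjusted p 0.0224), differences that the deletion of the gene itself sets. At 30 min the response in the DPL1 deletion minus that in the double deletion was -2.70 ± 0.45 for MET17 (adjusted p 0.0117), -2.71 ± 0.46 for MMP1 (adjusted p 0.0117) and -2.79 ± 0.52 for MET2 (adjusted p 0.0237).

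As a list, the 28 genes of methionine and sulfur assimilation differed in their response at 30 min by a median of 1.23 between the double deletion and the parental strain (adjusted p 0.00355 with an estimated correlation) and of -1.26 between the DPL1 deletion and the double deletion (0.00371). A single aberrant array is argued against, since the median was 1.173 in replicate 2 and 1.33 in replicate 1, and leaving out any 1 of the 8 arrays gave adjusted p from 0.00394 to 0.0411. RNA quality of the arrays is argued against as well, since with 3 control signals as covariates beside the replicate block the median was 1.022 times that without them (1.26 against 1.23). Centring on the hybridisation controls ended the list's call (median 1.44, adjusted p 0.170), and the cause was not tested. An effect of lacking LCB4 and LCB5 on these genes in heat stays open as a hypothesis: the tests that bear on it are the list's difference from the parental strain (0.0334 when adjusted over all 666 list tests) and that between the DPL1 deletion and the parental strain (median -0.17, adjusted p 0.988), both on the 2 arrays per group in which it was found.

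For the 1104 genes called over all times between the double deletion and the parental strain, strains were swapped at random within time and replicate number. Of 100 such splits 1, the real one, gave as many calls, and the highest other gave 4 (for the deletion strains 1 of 100, 725 against 0). These splits break up the time courses, so a lasting difference between courses of any origin would also set the real split apart. They argue against a random assignment of single arrays, but not against differences between courses. In the DPL1 deletion against the parental strain the single call is the deleted gene itself, so such splits decide nothing there. Of the 3 splits of the 4 whole time courses 2 gave as many, the real one and that by replicate number, with 1880, while the crossed split gave 0, which is too few splits for a share under 0.05; with the replicate number as a block the real count was 1919. Differences between single time courses stay open, since the fits with courses as random blocks part: 0.9303 of the genes were still called beside the replicate block, but 0.019 without it. RNA quality is argued against as the whole cause, since with 3 control signals as covariates beside the replicate block the genes kept a median share of 0.8603 of their difference (quartiles 0.727 and 0.993), while the calls went from 1796 with that block alone to 1095, which hold 762 of the 1104. An effect of the deletion on these genes stays open as a hypothesis, and the fits that bear on it, with the mean of each course as 1 sample, called 1 gene without a replicate block and 145 with it (53 higher and 92 lower, against 721 and 383), 118 of them among the 1104.

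Probe set 3982_at, for which the annotation lists no gene and which entered no comparison of genes, averaged 3.77 ± 1.31 (SD, n = 14) in the parental strain, 12.3 ± 0.24 in the DPL1 deletion and 12.7 ± 0.22 in the double deletion, higher over all times by 8.49 and 8.92 than in the parental strain; where the parental signal is background these are lower bounds, and the parental mean includes the array at 8.15. The 28 deletion arrays read 11.8 or more and 13 of the 14 parental arrays between 3.08 and 4.27, while the parental replicate 1 before heat read 8.15. Probe set 3954_at, also without a listed gene, was higher in the DPL1 deletion than in the parental strain over all times by 0.76 ± 0.09 (adjusted p 7.89e-05), with 9.90 as its lowest array against 9.84 as the highest parental one. Whether the parental replicate 1 before heat held some RNA of a deletion strain is not settled by these values, and it is 1 of only 2 parental arrays before heat; without it 24 genes in place of 6 were called before heat between the double deletion and the parental strain.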

How the results depend on the processing

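The course means, the random course beside the replicate block, each replicate number alone, the genes without non-coding and mitochondrially encoded ones and the arrays without the double deletion's 10 min replicate 2 were chosen after seeing the data, the other alternatives before. Of the counts of genes and lists under these alternatives 465 lay within 1.5 times the value in the report and 119 did not, and of those with 1 array left out 251 did and 57 did not. For single named genes 3605 results kept their direction and side of the threshold, 188 lost the call, 24 gained it and 0 reversed, and with 1 array left out 4828 kept both, 57 lost the call, 7 gained it and 0 reversed. Unless the alternative itself tests fewer genes or arrays or a lower threshold, the cause was not tested. With 2 arrays a group, small differences at a single time are near the limit of the design, and dim genes lie near background, where array signal limits their differences. Where 1 array was left out, the lone array is assumed to vary like the other groups. The values that moved by over 1.5 times follow.

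Centring on the hybridisation controls gave, for the heat response at any time and at 5, 10, 15, 20, 25 and 30 min, 776, 119, 480, 799, 995, 599 and 513 genes in the parental strain. It gave 727, 189, 578, 685, 795, 693 and 494 in the DPL1 deletion and 616, 181, 524, 625, 553, 407 and 298 in the double deletion. In that order for before heat, difference in heat response and all times, it gave 0, 0 and 112 for the double deletion against the parental strain and 1, 0 and 94 for the DPL1 deletion against the double deletion; the DPL1 deletion against the parental strain gave 1 (RDN18-1) in heat response. For the double deletion against the parental strain, median centring gave 3 before heat, cyclic loess 0 in heat response, and array weights 10 before heat and 0 in heat response.

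Without the dimmest 25% of genes the double deletion against the parental strain gave 2 before heat, and the deletion strains gave 5 before heat and 1 in heat response. An adjusted p under 0.01 left 452, 519 and 487 genes at 5 min in the parental strain, the DPL1 deletion and the double deletion, and 846 at 30 min in the double deletion. It left 2, 0 and 436 for the double deletion against the parental strain and 4, 1 and 262 between the deletion strains. All probe sets tested singly gave 2 before heat and 3 over all times for the DPL1 deletion against the parental strain, and 5 and 1 between the deletion strains before heat and in heat response. With only the groups compared there were 424 genes at 5 min in the parental strain, 875 at 30 min in the double deletion, 0 before heat and 0 in heat response for the double deletion against the parental strain, and 2 and 1 between the deletion strains. Without the double deletion's 10 min replicate 2 the deletion strains gave 1 in heat response.

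With the replicate block within strains, which follows the pairing of the arrays, the 5 min count was 1249 in the parental strain. It was 1302 in the DPL1 deletion and 1444 in the double deletion. For strain differences over all times this block takes the spread between a strain's courses out of the error. The DPL1 deletion against the parental strain gave 5 over all times (1 with the block across strains or with course means and a block), the double deletion against the parental strain 22 before heat and 1919 over all times, and the deletion strains 26, 5 and 1599. With the replicate block across strains the double deletion against the parental strain gave 10, 2 and 1796 and the deletion strains 15, 6 and 1430. A random course block beside that replicate block gave 1234, 1269 and 1445 at 5 min, 11 before heat and 2 in heat response for the double deletion against the parental strain, and 15 and 7 between the deletion strains. Beside the changes given here and in the report, the replicate block changed no other call of a gene or list described there, and it moved calls of some lists not described, such as purine synthesis. The random block alone gave 1275 and 1415 at 5 min in the DPL1 deletion and the double deletion, 4 in heat response and 21 over all times for the double deletion against the parental strain, and 8 and 28 between the deletion strains. Course means gave 1 and 2 over all times in these comparisons, and 145 and 101 with a replicate block. Within replicate number 1 and 2 alone, the DPL1 deletion against the parental strain gave 16 and 2 over all times and the deletion strains 415 and 1260.

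Of the 37 lists, an estimated correlation left 2, 2, 0, 0, 1 and 1 called at 5 to 30 min in the parental strain, and 0, 0 and 2 in the mean heat response of the parental strain, the DPL1 deletion and the double deletion (26, 24 and 22 by camera at the preset correlation). Before heat, over all times and in the mean difference in heat response it left 0 in each of the 3 strain comparisons, where the preset correlation gave 7, 13 and 4 for the DPL1 deletion and 12, 11 and 7 for the double deletion against the parental strain, and 14, 8 and 15 between the deletion strains. By fry the counts were 0, 0 and 0, then 0, 6 and 0, and 0, 3 and 0 in that order.

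Leaving out 1 array at a time gave 432 to 536 genes at 5 min, 1219 to 1551 at 10 min and 1225 to 1853 at 30 min in the parental strain, 459 to 572 and 1328 to 1860 at 5 and 30 min in the DPL1 deletion, and 413 to 819 and 559 to 1495 in the double deletion. For the DPL1 deletion against the parental strain the ranges were 1 to 6 before heat and 0 to 1 in heat response, for the double deletion against the parental strain 2 to 24 and 0 to 2, and between the deletion strains 4 to 12 and 0 to 4, with 448 to 972 over all times.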

Other observations

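The tests on non-coding genes were all planned before their results were seen.

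The alpha-specific genes STE3 and MF(ALPHA)1 are given here as levels, and no difference in their heat response between the double deletion and the parental strain was shown. STE3, the a-factor receptor, went from 8.42 ± 0.95 (SD, n = 2) before heat to 4.04 ± 0.41 at 15 min and 5.55 ± 0.95 at 30 min in the parental strain, and from 8.01 ± 0.16 to 5.18 ± 0.10 and 6.22 ± 0.73 in the double deletion. The pheromone gene MF(ALPHA)1 went from 12.2 ± 0.19 to 9.31 ± 0.29 and 8.77 ± 1.46 in the parental strain and from 12.2 ± 0.03 to 9.27 ± 0.28 and 10.5 ± 1.05 in the double deletion. Neither was called by the joint test, and the difference in mean response of the alpha-specific list had a median of 0.43 and was not called (adjusted p 0.136, and 0.73 with an estimated correlation).

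HIS4, of histidine synthesis, varied between the replicates of the parental strain and of the DPL1 deletion. At 5 min it read 8.30 ± 1.98 and 8.08 ± 1.73 in these strains, against 6.57 ± 0.10 in the double deletion. URA3 fell with heat in each strain, by 1.92, 1.92 and 1.07 (log2) in the parental strain, the DPL1 deletion and the double deletion, while TRP1 rose by 1.00, 0.91 and 0.61.

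Non-coding and mitochondrially encoded genes were lower in replicate 2, with a median of -0.85 over 91 tRNA genes. Within replicate 2 this signal was not seen to follow RNA degradation, as measured by the SRB4 difference between its 3' and 5' ends. Over the 21 replicate 2 arrays the mean of 189 such genes correlated with it at 0.0293 (two-sided permutation p 0.902, adjusted 0.902). The Spearman correlation was -0.058 (permutation p 0.803, adjusted 0.803), and r was -0.106 without the 2 arrays farthest from the median. Replicate 1 was not in this test, and the SRB4 difference averaged 0.52 in replicate 1 and 1.97 in replicate 2. Degradation as a source of the difference between replicates therefore stays open. Less RNA without a poly(A) tail in the labelled material may be an explanation. Over the replicate 2 arrays alone, the mean of these 189 genes correlated with the 18S signal at 0.7838 (permutation p 2e-05, adjusted 4e-05). The Spearman correlation was 0.660 (permutation p 0.00171, adjusted 0.00342), and r was 0.638 without the 2 arrays farthest from the median. The 189 genes held 4 ribosomal RNA genes, so that mean and the 18S control both measure ribosomal RNA in part. They also held 11 pseudogenes, with a median of 0.17 for replicate 2 minus replicate 1. The relations with the SRB4 difference and with the 18S signal were the 2 of the family tested, and no biological explanation was tested.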
